A study of Caenorhabditis elegans with 6 samples.

How the data were processed

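Genomic DNA from embryos was compared on NimbleGen whole-genome tiling arrays. Per the labels' protocols, strains with the same transgene, inserted in single copy and coding for either Dam fusion, were grown in parallel in 3 biological replicates per genotype. Each culture of 35000 synchronised larvae was grown in 50 mL at 20 °C for 66 h with a Dam-negative Escherichia coli strain as food. DNA was purified from 30 mg of embryos, methylated fragments were amplified from 5 µg of it by digestion with DpnI and DpnII, adaptor ligation and PCR, and 1 µg of each product was labelled. LMN-1-Dam and GFP-Dam products of the same genotype and replicate were hybridised to the same array. Per the labels, LMN-1-Dam carried Cy3 in replicates 1 and 2 of each genotype and Cy5 in replicate 3.

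The deposited values are per-probe log ratios, used here as log2 ratios, 1 table per array, with 2033813 probes and no missing value. The log base, the normalization, the centring, any probe filter and the genome build are not given in the sources used here. If the base were not 2, every size given as log2 would be on another scale, while tests and calls would stay as they are. The direction, LMN-1-Dam over GFP-Dam, is taken as likely from the sample titles, which name LMN-1 before GFP. Arrays of opposite dye orientation correlated positively with each other, with between 0.0325 and 0.347 over probes. All 6 tables were therefore taken to run the same way, and no sign was turned here. The array medians over probes ran from -0.083 to 0.090. Channel intensities were not used here, so background and saturation could not be examined.

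Probes were averaged in 100 kb bins with at least 100 probes, which kept all 1005 bins (401 to 2386 probes per bin). A chromosome's length was taken as its largest probe coordinate, arms as the outer 25% at each end and the centre as the middle 50%. This gave 18 regions, each the mean of its bins. Coordinates are those of the deposited tables. The bins were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with genotype as the only term, two-sided, and Benjamini-Hochberg adjusted p under 0.05 counted as a call. The same model was fitted to the 18 regions and to the arm minus centre differences of the 6 chromosomes, and the genotype means were tested against 0. In the fits over regions and chromosomes all rows share 1 estimate of the spread and regions of an array share its errors, so their adjusted p-values are likely too small. Single values per array were compared by exact two-sided permutation tests, where 3 against 3 arrays cannot go below 0.1, and against 0 by exact sign-flip tests, where 3 arrays cannot go below 0.25. Tables were made with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures with matplotlib 3.10.9.

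The fit was tested on simulated data with the real means and spreads of the 1005 bins, in which 200 bins were changed. It recovered 41.0% of changes of 0.4 and 87.0% of changes of 0.8, with 1.54% of the calls false. With an added random offset per chromosome and array it recovered 36.0% and 90.0%, with 3.82% false. Neither setting held errors shared by the arms of an array beyond this offset. Among the wild-type arrays the arm minus centre difference was 0.83, 0.83 and 0.57. The false shares do not cover a spread of that kind.

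The design, the alternatives and the rule for named bins were set before the data were examined. The rule took the 5 called bins with the largest fall and the 5 with the largest rise whose 3 values per genotype do not overlap, and the 3 highest and 3 lowest bins in wild type. The called bins of X, the test of each chromosome's arm minus centre change and the test of autosomes against X were added after the values were seen. Alternatives were array scaling (median centring, median centring with division by the SD over 100 kb bins, quantile normalization), each array left out in turn, the replicate number as a block, the dye orientation as a covariate, other eBayes settings, other bin sizes, probe medians, other arm definitions (wider arms, and boundaries written from memory of the published recombination map), and domains without smoothing or with other thresholds. Removal of each array's chromosome means and removal of both replicate 3 arrays were added after the data were seen. Tests of single genes and of gene lists had been planned on the condition that an annotation fits the coordinates. They were not run, because the build of the coordinates is not given in the sources used here, so the values at met-2, set-25 and lmn-1 are not reported here. Since both channels of an array carry the same genotype, the ratio does not check the genotype label of an array.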

Results

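Contact between the genome and the nuclear lamina was mapped by DamID in early embryos of the nematode Caenorhabditis elegans. DamID fuses the bacterial Dam methyltransferase to a protein of interest, so that adenines in nearby GATC sites become methylated. Here Dam was fused to LMN-1, the lamin of C. elegans and the main filament protein of the nuclear lamina, and free GFP-Dam served as the control for accessibility and background methylation. The 6 arrays fell into 2 genotypes with 3 biological replicates each. The genotypes were wild type (N2) and a double mutant of set-25(n5021) and met-2(n4256), which lacks 2 histone methyltransferases. MET-2 is known for mono- and dimethylation of histone H3 lysine 9 and SET-25 for its trimethylation. Each array compared LMN-1-Dam with GFP-Dam material of the same genotype, so a change between genotypes is a difference between ratios. Each array gave a log2 ratio for 2033813 probes with a median spacing of 40 bp, and a 100 kb bin held a median of 2113 probes. The precision was limited by the number of arrays.

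The arrays of each genotype were compared with each other first. Across the 1005 bins of 100 kb, Pearson correlations ran from 0.713 to 0.909 among the wild-type arrays, from 0.815 to 0.916 among the mutant arrays and from 0.517 to 0.862 between genotypes. Single probes were much noisier, with correlations of 0.219 to 0.549 among wild-type arrays and 0.322 to 0.347 among mutant arrays. These correlations are across genome positions, which are not independent replicates. The SD over 100 kb bins was 0.549, 0.596 and 0.401 in wild-type replicates 1 to 3, and 0.359, 0.344 and 0.420 in mutant replicates 1 to 3. The ratios are relative and their centring is not given in the sources used here, so 0 is not an absolute level of lamina contact.

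In wild-type embryos the chromosome arms carried a higher LMN-1 ratio than the chromosome centres. With arms taken as the outer 25% of the length at each end, the arms averaged 0.47 ± 0.066 (SD, n = 3) and the centres -0.27 ± 0.092. The arm minus centre difference was 0.74 ± 0.15 and positive on 3 of 3 arrays, with 0.83, 0.83 and 0.57 in replicates 1 to 3. Its exact two-sided sign-flip p was 0.25, the smallest that 3 arrays allow. All 5 autosomes showed the difference, with 0.88 ± 0.12 on chromosome I, 0.86 ± 0.18 on II, 0.87 ± 0.14 on III, 0.71 ± 0.21 on IV and 0.83 ± 0.22 on V. On the X chromosome it was 0.36 ± 0.083. Each of these 6 values was above 0 in limma, with the largest Benjamini-Hochberg adjusted p, 4.46e-05, on X. In wild type, 428 of the 1005 bins passed the limma test as above 0 (adjusted p under 0.05), 338 passed as below 0 and the others did not pass. The share that passed as below 0 went from 33.6% to 21.9% without wild-type replicate 1. Those called above 0 comprised 384 of the 414 autosomal arm bins, 31 of the 413 autosomal centre bins and 13 of the 178 X bins. The highest wild-type bins lay in the right arm of V, at 17.4-17.5 Mb with 1.30 ± 0.58, at 17.1-17.2 Mb with 1.10 ± 0.34 and at 19.3-19.4 Mb with 1.08 ± 0.30. The lowest lay in the centres of I at 7.5-7.6 Mb with -0.88 ± 0.41, of II at 7.6-7.7 Mb with -0.87 ± 0.51 and of V at 6.2-6.3 Mb with -0.85 ± 0.63.

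**Figure D1:**
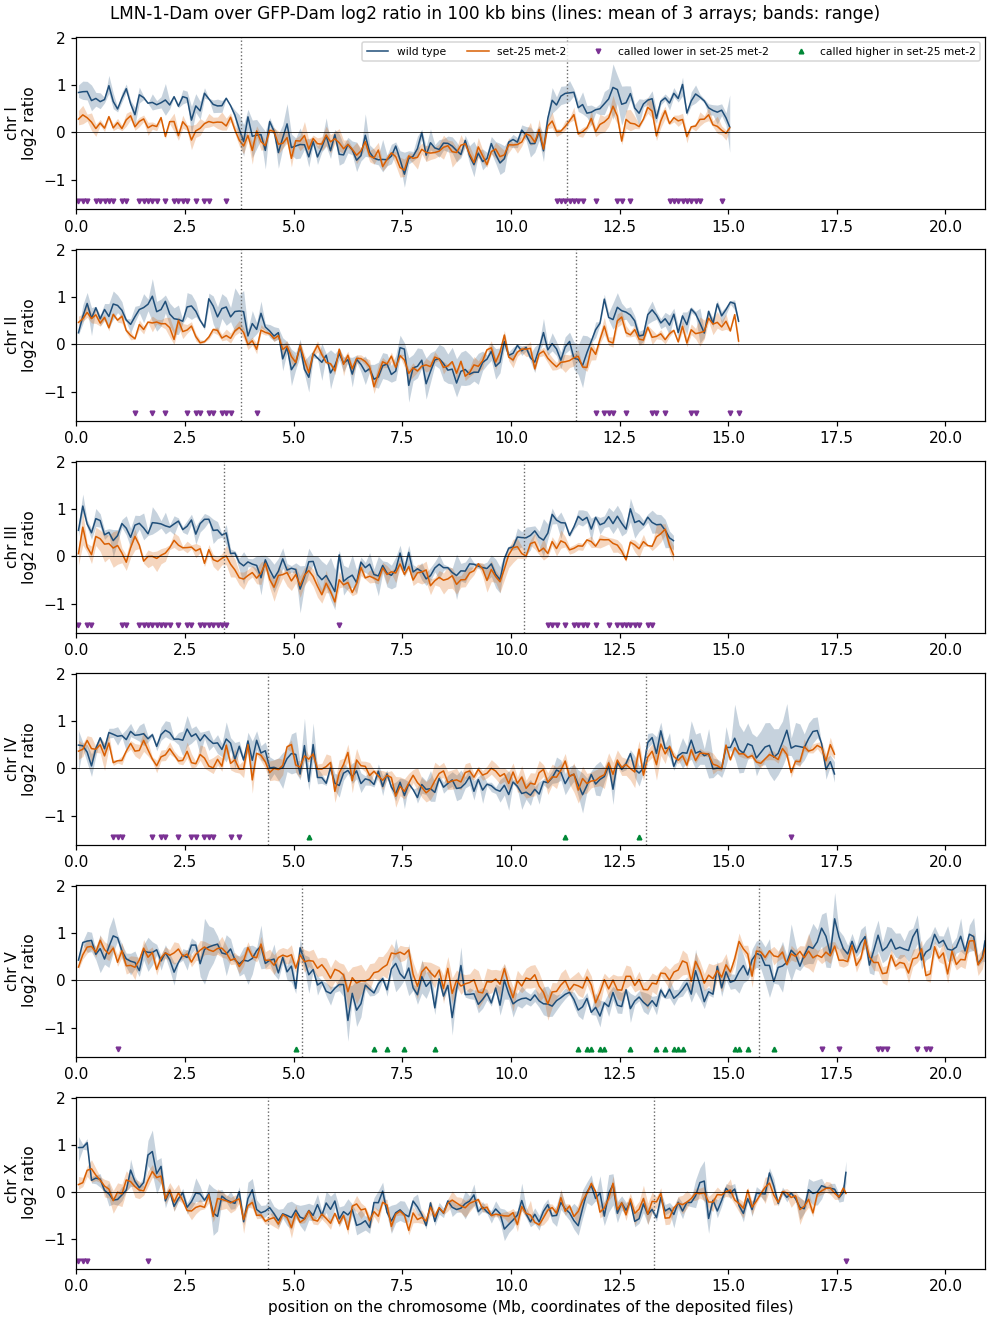
The LMN-1-Dam over GFP-Dam log2 ratio (vertical axis) is plotted against position in Mb (horizontal axis) for the 1005 bins of 100 kb on the 6 chromosomes. Lines are means of 3 arrays, bands are the range of the 3 arrays, dotted lines part arms from centre, and triangles mark the 139 bins called lower and the 23 called higher in the mutant, which lie mainly in the arms of I to IV and the centre of V.

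The question of the comparison between genotypes is whether lamina contact changes when these 2 histone methyltransferases are missing. In the double mutant the arms averaged 0.23 ± 0.053 (SD, n = 3) against 0.47 in wild type, and the centres -0.22 ± 0.067 against -0.27. The arm minus centre difference was 0.45 ± 0.015 in the mutant, which is 60.2% of the wild-type value. All 3 mutant arrays lay below all 3 wild-type arrays. The exact two-sided permutation p for the change of -0.30 was 0.1, the smallest that 3 against 3 arrays allow, and the Benjamini-Hochberg value over the 5 contrasts of this kind was 0.25. The arm minus centre difference of the mutant was positive on 3 of 3 arrays (sign-flip exact p = 0.25). After quantile normalization of the arrays the change was -0.11, on a wild-type difference of 0.64, with an exact permutation p of 0.4. After SD scaling the change was -0.24, on a wild-type difference of 1.44, both in units of the array SD (exact permutation p = 0.1). The relative fall was thus smaller under both scalings. The SD over 100 kb bins contains the arm to centre contrast itself, and quantile normalization gives all arrays the same distribution. Either scaling can therefore take away part of a real change of contrast, so the smaller fall does not count against one.

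Chromosome by chromosome, the arm minus centre difference was lower in the mutant on every autosome in limma. The log2 change was -0.40 on I (SE 0.10, adjusted p = 0.00222), -0.30 on II (adjusted p = 0.0116), -0.29 on III (adjusted p = 0.0128), -0.33 on IV (adjusted p = 0.00713) and -0.41 on V (adjusted p = 0.00222). On X the values were 0.36 in wild type and 0.32 ± 0.098 in the mutant, with a change of -0.045 (adjusted p = 0.664) whose sign turned after SD scaling or quantile normalization. Without both replicate 3 arrays, an alternative chosen after the data were seen, the X change was -0.14 and passed the test (adjusted p = 0.0398). The autosomal difference exceeded the X difference by 0.46 ± 0.13 in wild type and by 0.16 ± 0.12 in the mutant. The exact permutation p for this change of -0.31 was 0.1, with no overlap between the genotypes; after quantile normalization it was -0.19 with an exact permutation p of 0.2. No autosome passed after quantile normalization (smallest adjusted p = 0.263), and only I and V passed after SD scaling (adjusted p = 0.0179 for both). Calls on II, III or IV were also lost without wild-type replicate 1, wild-type replicate 2 or mutant replicate 1, with adjusted p from 0.0593 to 0.0757 in those cases.

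**Figure D2:**
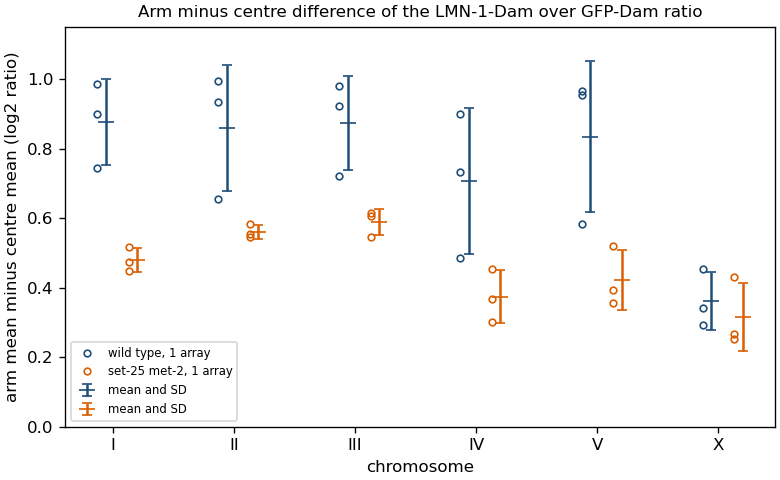
The mean log2 ratio of the arm bins minus that of the centre bins (vertical axis) is shown per chromosome (horizontal axis) for each of the 3 arrays of a genotype (open circles), with the mean and SD beside them. The 3 mutant arrays sit below the 3 wild-type arrays on I to V, while on X the arrays of the genotypes overlap at 0.36 and 0.32 on average.

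When each chromosome was divided into left arm, centre and right arm, 7 of the 18 regions were lower in the mutant and 1 was higher (limma, adjusted p under 0.05). All 7 lower regions were autosomal arms. The left arm of III went from 0.62 ± 0.043 to 0.14 ± 0.16, a log2 change of -0.49 (SE 0.099, adjusted p = 6.73e-05), which puts the ratio at 0.714 of wild type. The left arm of I went from 0.64 ± 0.049 to 0.16 ± 0.089 and changed by -0.48 (adjusted p = 6.73e-05). The right arms of I and III changed by -0.41 each (adjusted p = 0.000404 for both). The arms of II changed by -0.32 on the left (adjusted p = 0.00653) and -0.29 on the right (adjusted p = 0.00956), and the left arm of IV by -0.30 (adjusted p = 0.00818). The higher region was the centre of V, which went from -0.24 ± 0.069 to 0.076 ± 0.21, a change of 0.31 (adjusted p = 0.0070). The left arm of V had the same mean in both genotypes within error, 0.52 ± 0.13 in wild type and 0.52 ± 0.13 in the mutant. Its arrays went in opposite directions. Replicates 1 and 2 were at 0.59 and 0.60 in wild type and 0.41 and 0.49 in the mutant. Replicate 3 was at 0.38 in wild type and 0.67 in the mutant. The right arms of V and IV had changes of -0.19 (adjusted p = 0.106) and -0.12 (adjusted p = 0.341), and both signs turned after SD scaling or quantile normalization. Both were called lower without wild-type replicate 3, at -0.31 (adjusted p = 0.00823) for V and -0.23 (adjusted p = 0.0493) for IV, and without both replicate 3 arrays, at -0.39 (adjusted p = 0.000523) and -0.28 (adjusted p = 0.00973). The right arm of V was also called without mutant replicate 3, at -0.27 (adjusted p = 0.0254), and with arm boundaries recalled from the recombination map, at -0.26 (adjusted p = 0.0184). With wider arms the left arm of IV lost its call, at -0.21 (adjusted p = 0.0703), which left 6 lower regions. The 3 X regions had changes of -0.11, -0.014 and -0.014 for the left arm, centre and right arm (smallest adjusted p = 0.403). Median centring of the arrays left 4 lower regions, the arms of I and III, quantile normalization left 2, the left arms of I and III, and SD scaling left none. The call on the centre of V was lost after SD scaling (adjusted p = 0.0869), and without mutant replicate 2 (change 0.32, adjusted p = 0.0687), mutant replicate 3 (0.20, adjusted p = 0.101) or wild-type replicate 1 (0.27, adjusted p = 0.0636). The centre of III was called lower without wild-type replicate 2, at -0.25 (adjusted p = 0.0458), and 4 lower regions remained without wild-type replicate 1.

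**Figure D3:**
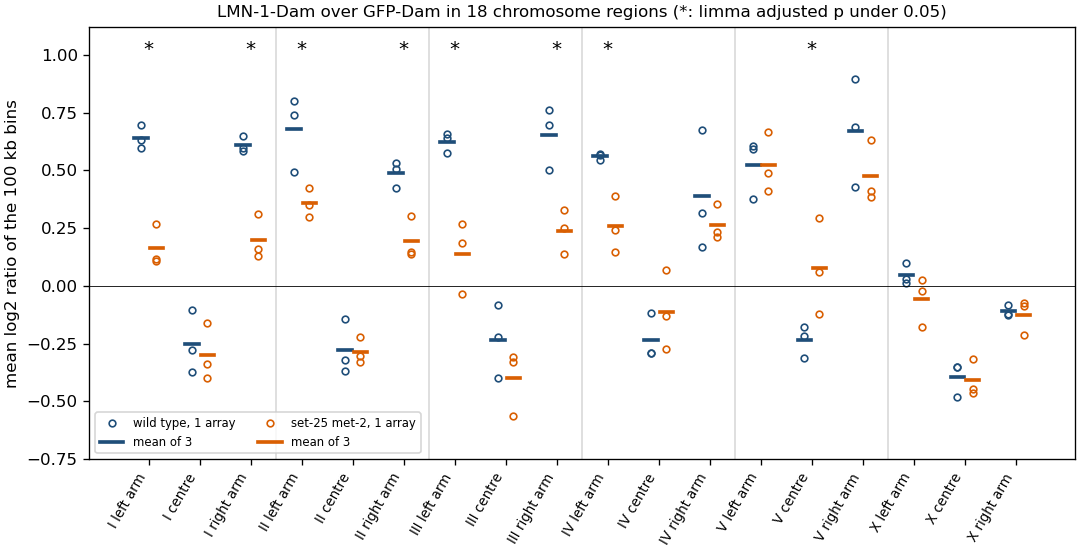
The mean log2 ratio of the 100 kb bins of a region (vertical axis) is shown for 18 chromosome regions (horizontal axis), with open circles for single arrays and bars for the mean of 3 arrays. Stars mark the 8 regions called in limma; in the 7 starred arms every mutant array lies below every wild-type array, and in the centre of V every mutant array lies above.

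At 100 kb resolution, 139 of the 1005 bins (13.8%) were lower in the mutant and 23 (2.29%) were higher (limma, adjusted p under 0.05). Of the lower bins, 133 lay in arms and 128 of these in autosomal arms, where they made up 30.9% of the bins. The left arm of III (22 of 34 bins) and the left arm of I (24 of 38 bins) had the highest shares. Of the higher bins, 21 lay in centres, 18 of them in the centre of V and 3 in the centre of IV. Of the 428 bins called above 0 in wild type, 138 were lower in the mutant, and 235 also passed the test against 0 in the mutant, where 267 bins passed as above 0 in all. By chromosome, 25 of the 80 such bins on I passed it in the mutant too, 22 of 72 on III, 46 of 78 on II, 40 of 80 on IV and 95 of 105 on V, where 119 bins passed in the mutant in all. The share of bins that passed as above 0 in the mutant went from 26.6% to 15.5% without mutant replicate 2 and 15.4% without mutant replicate 3. A bin that did not pass in the mutant can still have a mean above 0, as the arms of I and III did on average. The values of the genotypes did not overlap in 249 bins on the lower side and 81 on the higher side. Chance gives 10% of the bins over both sides together on average over groupings of the arrays. Bins of an array share its errors, so a single grouping can lie far from that share. These counts are therefore no test against chance. The balance of lower and higher calls depended on the scaling, with 46 lower and 27 higher after median centring, 12 and 31 after SD scaling and 33 and 58 after quantile normalization. Leaving out mutant replicate 2 or 3 gave 0 calls in limma (195 lower and 45 higher, and 192 lower and 27 higher, at unadjusted p under 0.05), while the counts were 4 lower and 0 higher without wild-type replicate 1, 38 and 9 without mutant replicate 1, and 223 and 94 without wild-type replicate 3. They were 27 and 13 with each array's chromosome means removed and 87 and 15 with probe medians.

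The 5 bins with the largest called falls all lay in arms. On III, 2.9-3.0 Mb (1874 probes) went from 0.78 ± 0.16 (SD, n = 3) to -0.15 ± 0.060, a log2 change of -0.93 (SE 0.14, limma adjusted p = 0.00268). On II, 3.0-3.1 Mb went from 0.96 ± 0.13 to 0.15 ± 0.046 (adjusted p = 0.00691). The left end of X, 0-0.1 Mb, went from 0.94 ± 0.27 to 0.16 ± 0.15 (adjusted p = 0.0103). On I, 12.5-12.6 Mb changed by -0.78 and 2.0-2.1 Mb by -0.77 (adjusted p = 0.0103 for both). The 5 bins with the largest called rises all lay in the centre of V. There, 12.7-12.8 Mb went from -0.60 ± 0.31 to 0.082 ± 0.20 (change 0.68, SE 0.17, adjusted p = 0.0148), 8.2-8.3 Mb from -0.58 ± 0.19 to 0.068 ± 0.25 (adjusted p = 0.0148) and 13.9-14 Mb from -0.19 ± 0.16 to 0.41 ± 0.27 (adjusted p = 0.0196). The bins at 11.8-11.9 Mb and 13.7-13.8 Mb rose by 0.58 and 0.55 (adjusted p = 0.0172 and 0.0208). Each of these 10 bins kept the direction of its change under the 3 array scalings that were tried, and lost its call without mutant replicate 2 or mutant replicate 3, as did 7 of them without wild-type replicate 1. The changes themselves were 93.7% to 107% of the values given without mutant replicate 2, 79.7% to 111% without mutant replicate 3 and 78.5% to 118% without wild-type replicate 1. With each array's chromosome means removed, 5 of the 10 bins lost their call, those on I and those on V at 12.7-12.8 Mb, 8.2-8.3 Mb and 13.7-13.8 Mb, with adjusted p from 0.0514 to 0.0815. The changes of the 10 bins were then 67.0% to 95.3% of the values given. The wild-type peaks on V at 17.1-17.2 Mb and 19.3-19.4 Mb changed by -0.62 and -0.60 (adjusted p = 0.0214 and 0.0219), and the highest bin, at 17.4-17.5 Mb, changed by -0.58 without passing the test (adjusted p = 0.0610).

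Within the autosomal arms, the outer and inner parts on either side of the middle of an arm had changes of similar size. The outer part went from 0.61 ± 0.075 to 0.33 ± 0.047 and the inner part from 0.55 ± 0.074 to 0.27 ± 0.045. The outer minus inner difference was 0.066 ± 0.0041 in wild type and 0.064 ± 0.0019 in the mutant (exact permutation p = 0.6). With the outermost 5% of the chromosome set against the rest of the arm, the change of that difference was 0.072 (exact permutation p = 0.1).

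The X chromosome as a whole lay below the autosomes in both genotypes. Its mean minus the autosomal mean was -0.38 ± 0.021 in wild type and -0.31 ± 0.027 in the mutant. The change of 0.071 had an exact permutation p of 0.1 (0.25 after Benjamini-Hochberg adjustment) and its sign turned after SD scaling or quantile normalization. Only 5 of the 178 X bins were called, all lower in the mutant. Of these, 3 formed the first 0.3 Mb of the left end, where 0.1-0.2 Mb went from 0.95 ± 0.056 to 0.20 ± 0.10 and 0.2-0.3 Mb from 1.04 ± 0.14 to 0.46 ± 0.11 (limma adjusted p = 0.0103 and 0.0156). The other calls were at 1.6-1.7 Mb, with a change of -0.54, and in the last bin, with a change of -0.44 (adjusted p = 0.0316 and 0.0489). That last bin is short, at 17.7-17.719 Mb, and held 401 probes, the fewest of any bin.

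With 10 kb bins smoothed over 5 bins, 53.4% ± 1.74 (SD, n = 3) of the bins were above 0 in wild type and 52% ± 4.70 in the mutant (exact permutation p = 0.8), a difference within the spread between arrays. Without the smoothing the share was lower on every mutant array than on any wild-type array, with a change of -3.66 percentage points and an exact permutation p of 0.1. With a threshold of 0.25 in place of 0 the share was 11.7 percentage points lower in the mutant, with an exact permutation p of 0.1. The sign of the smoothed difference at a threshold of 0 turned after median centring, SD scaling and quantile normalization.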

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

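The arrays left out as a pair (both replicate 3 arrays), the removal of chromosome means, and the alternatives for shares above or below 0, for the chromosome-wise changes and for autosomes against X were chosen after the data were seen. The genome-wide arm minus centre change stayed below 0 under the alternatives run for it (scalings, arrays left out, block and arm definitions). On the log2 scale it ran from -0.38 without both replicate 3 arrays to -0.11 after quantile normalization, and from -0.38 to -0.25 with single arrays left out. The wild-type difference ran from 0.64, after quantile normalization, to 0.83 on the log2 scale. In units of the array SD the wild-type difference was 1.44 and the change -0.24. Because SD scaling and quantile normalization can absorb part of a real change of contrast, calls lost under them do not decide whether it is real. The cause of the changes below was not tested. The share of bins called lower was 4.58% after median centring, 1.19% after SD scaling, 3.28% after quantile normalization, 8.66% with probe medians, 2.69% with chromosome means removed and 0% with 10 kb bins. The share called higher was 5.77% after quantile normalization, 4.18% with a dye term, 5.91% in 500 kb bins, 1.49% with probe medians, 1.29% with chromosome means removed, 5.67% without both replicate 3 arrays and 0% with 10 kb bins. With 10 kb bins limma had 1318 lower and 534 higher bins of 10011 at unadjusted p under 0.05. With single arrays left out, the share lower ran from 0% to 22.2% and the share higher from 0% to 9.35%. Without mutant replicate 2 or 3 the smallest adjusted p was 0.0516 or 0.0677, and the 139 lower bins of the full set still had changes below 0. All 46 bins called lower after median centring were among those 139, as were 11 of the 12 after SD scaling and 29 of the 33 after quantile normalization. Requiring no minimum of probes removed no bin and says nothing. Shares of bins above and below 0 ran from 37.9% to 43.4% and from 21.9% to 34.7% in wild type, and from 15.4% to 32% and from 16.9% to 31.2% in the mutant, with single arrays left out.

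The number of lower regions was 4 after median centring, 0 after SD scaling and 2 after quantile normalization, and 4 to 9 with single arrays left out. The number of higher regions was 0 after SD scaling and 0 to 1 with single arrays left out. At unscaled values, 7 lower regions and 1 higher region also stood with a dye term. Regions without a call changed sign as follows. After median centring the changes were 0.023 in the centre of I, 0.062 in the centre of II, 0.067 in the left arm of V, 0.056 in the centre of X and 0.055 in its right arm. After SD scaling they were 0.16 in the right arm of IV, 0.54 and 0.15 in the left and right arms of V and 0.051 in the right arm of X, and after quantile normalization 0.066, 0.24, 0.065 and 0.0074 in the same 4 regions. With wider arms they were 0.012 in the centre of I, 0.062 in that of II, 0.081 in the left arm of V and 0.0013 in the centre of X. With arm boundaries recalled from memory of the recombination map they were 0.0047 in the centre of II, 0.030 in the left arm of V and 0.0059 in the centre of X. Without both replicate 3 arrays they were 0.077, 0.082 and 0.035 in the centres of I, II and X. With single arrays left out the ranges were -0.12 to 0.027 (centre of I), -0.053 to 0.060 (centre of II), -0.23 to 0.022 (right arm of IV), -0.077 to 0.053 (left arm of V), -0.061 to 0.013 (centre of X) and -0.040 to 0.030 (right arm of X).

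For the single values, the outer minus inner change was 0.041 after SD scaling, 0.021 after quantile normalization, 0.072 with the outermost 5% as the outer part, and -0.0034 to 0.00031 with single arrays left out. The arm minus centre change of X was 0.13 after SD scaling and 0.046 after quantile normalization, and ran from -0.10 to 0.00039 with single arrays left out. The change of X against the autosomes was -0.066 after SD scaling and -0.033 after quantile normalization. The change of the share above 0 was 3.46 percentage points after median centring, SD scaling or with the array median as threshold, 2.63 after quantile normalization, -3.66 without smoothing, -11.7 with a threshold of 0.25, and -2.96 to 1.31 with single arrays left out.

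With the replicate number as a block, 11.7% of bins were lower and 2.39% higher, and the 8 called regions kept their calls. The deviations of same-numbered arrays from their genotype means correlated at 0.125, -0.281 and -0.034 over bins, so the numbers were not taken to pair the arrays, and only replicate 1 correlated best with its own number. The planned gene and gene-list alternatives (scalings, arrays left out, blocks, probe minimum, flanks, camera and fry settings, region means removed) were not run, as no gene values were made. Signal over background could not limit any value here, because intensities were not used.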

Other observations

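The tests on the arm to centre contrast by compression, by dye and by bins far from the boundary, those on chromosome offsets and the counts of splits were chosen after the results were seen; the bound for the position of the arm boundary was set before. The ends of the autosomes were compared with the rest of the arms. The outermost 5% at each end (85 bins) averaged 0.62 ± 0.056 (SD, n = 3) in wild type and 0.39 ± 0.070 in the mutant, a change of -0.23, while the rest of the arms (329 bins) went from 0.57 ± 0.080 to 0.27 ± 0.040, a change of -0.30. Each of these changes had an exact permutation p of 0.1, the smallest possible, and so did the difference between them, 0.072. In the centre of IV, 3 bins were called higher in the mutant: 5.3-5.4 Mb went from -0.28 to 0.19, 11.2-11.3 Mb from -0.32 to 0.15 and 12.9-13 Mb from -0.10 to 0.40 (limma adjusted p = 0.0384, 0.0403 and 0.0336).

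At 1 kb resolution the largest gap between genotypes, looked for after the data were seen, lay on X at 5912-5913 kb (10 probes), where the wild-type arrays were at or above 3.11 and the mutant arrays at or below -0.036. The next largest gaps with wild type above lay on III at 7635-7636 kb, where the wild-type arrays were at or above 2.13 and the mutant arrays at or below -0.605, and on I at 1156-1157 kb, with 2.83 and 0.30. On X, the neighbouring segments starting at 5908 and 5911 kb averaged 4.40 and 4.05 on the log2 scale in wild type, with all 3 arrays at or above 2.62, and stayed at or below 0.43 on each mutant array. Between them, the segment at 5909-5910 kb lay between 0.23 and 1.09 on the wild-type arrays, and that at 5910-5911 kb varied widely, at -1.99, 1.95 and -2.65 on the wild-type arrays and -2.59, -0.055 and -1.75 on the mutant arrays. Whether ratios of this size on X reflect lamina contact or a DNA difference between the strains was not tested. The widest gaps in the other direction lay on V at 10602-10603 kb, 15156-15157 kb and 7148-7149 kb, where wild-type arrays were at or below -1.04 and mutant arrays at or above 0.94.

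A dye bias of the swapped arrays is argued against as the source of the smaller arm minus centre difference in the mutant: among the 4 arrays with LMN-1-Dam in Cy3, the smallest gap between a wild-type and a mutant array was 0.369, while arrays of a genotype differed by at most 0.030. The size differed by orientation, with a mean change of -0.38 over those arrays and -0.12 between the 2 arrays with LMN-1-Dam in Cy5. A uniform compression of the mutant log ratios stays open. Divided by the probe SD within 1 kb, the difference was 1.10 ± 0.38 in wild type and 0.85 ± 0.035 in the mutant. The change was -0.248 with overlapping arrays (exact permutation p = 0.4), or -0.46 without wild-type replicate 3, which makes the overlap. That array had the largest SD within 1 kb, 0.847, and the smallest wild-type difference, 0.57. This SD thus also holds noise apart from the scale of the ratios, and the quotient cannot decide. Some means over all arrays are at odds with a single factor for all regions. The left arm of V was at 0.52 in both genotypes, and the centre of III at -0.24 and then -0.40. The centre of V, called higher, went from -0.24 to 0.076, past 0, where a single factor would keep the sign. Its mutant mean did not pass the test against 0 (limma adjusted p = 0.297). The X difference kept 87.5% of its size against 57.6% on the autosomes. But the last comparison had an exact permutation p of 0.1, and the centre of III was not called. These means also depend on the replicate 3 arrays. In replicates 1 and 2 the left arm of V was at 0.59 and 0.60 in wild type and 0.41 and 0.49 in the mutant. The centre of III was there at -0.22 and -0.40, then -0.33 and -0.31. The X difference was there 0.45 and 0.34, then 0.25 and 0.27. The centre of V was there at -0.31 and -0.22, then -0.12 and 0.058. The means therefore do not decide on compression. A moved arm boundary as the whole cause was examined in bins far from it. The outermost 10% at each end minus the middle 20% of the autosomes was 1.02 ± 0.22 in wild type and 0.66 ± 0.034 in the mutant. The change was -0.363 with no overlap (exact permutation p = 0.1). It goes against the boundary as the whole cause, but weakly. The lowest wild-type array was at 0.77 and the highest mutant array at 0.68, a gap smaller than the wild-type SD. The best split point over 10 autosomal arms lay at 27% ± 0.35 of the length in wild type and 28.9% ± 1.46 in the mutant, a shift of 1.85 percentage points away from the end (exact permutation p = 0.2), where the prediction was a shift towards it, so a contribution of the boundary stays open. A loss of lamina contact in the arms of the mutant, the genotype the design names, remains a candidate explanation beside compression. Channel intensities were not used here. A change of the LMN-1-Dam signal therefore cannot be told apart from a change of the GFP-Dam signal.

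Chromosome-wide offsets were compared between genotypes. Relative to the autosomal mean, V lay at 0.012 ± 0.091 in wild type and 0.25 ± 0.15 in the mutant, III at 0.033 ± 0.096 and -0.14 ± 0.14, and I at 0.021 ± 0.050 and -0.096 ± 0.084. The exact permutation p was 0.1 for V and 0.2 for III and for I, where the arrays of the genotypes overlapped. A dye bias is argued against, since it would move replicate 3 the same way in both genotypes, and the replicate 3 offsets correlated at -0.907 between genotypes over the 6 chromosomes (exact permutation p = 0.0111, chromosomes not being independent replicates). Whether mutant replicate 3 alone makes the pattern cannot be told apart: V minus the mean of I and III was 0.67 on that array and 0.21 and 0.22 on the other mutant arrays, which exceeded the highest wild-type array by only 0.0789, less than the wild-type SD of 0.15. A biological difference of the genotypes is untested here beyond these values.

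The calls were counted for other groupings of the arrays. Of the 10 splits of the 6 arrays into 3 and 3, 1 split, the real one, gave as many called bins (162, against at most 0 in the others), and 1 split gave as many called regions (8, against at most 0). With 10 splits the share cannot go under 0.05, so this count cannot exclude chance.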
